A study of Arabidopsis thaliana with 6 samples.

How the data were processed

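Messenger RNA levels were measured in whole shoots of 2-week-old plants, 3 wild-type Col-0 and 3 *hos15-4*, grown at 22 °C under constant light of 100 µmol per square metre and second and 50% humidity. Total RNA was extracted with TRIzol and sequenced with standard Illumina libraries, per the labels' protocols. The deposited table gives raw counts per gene and library, with no pooling of replicates. STAR, edgeR and the genome build TAIR10 are named without version or role, per the submitters' processing notes. The read counter, gene annotation, strand setting and any filter are not given in the sources used here. The table lists nuclear genes, and organelle genes were not analysed here.

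All gene identifiers were matched to the RefSeq TAIR10.1 annotation, which supplied symbols, coordinates, exon lengths, GC content and product texts. Coordinates in the text are from that annotation. Genes with overlapping exons were marked as uncertain. Near-identical copies of listed genes were searched with blastn 2.17.0 at a minimum of 95% identity over 50% of the exonic length. That identity minimum was lowered once from a stricter one that found fewer genes, before any test used it.

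Groups came from the genotype labels. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14068 genes, and scaled by TMM in edgeR 4.0.16 under R 4.3.3. The comparison used the quasi-likelihood test with genotype as its term, Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 9.95%. CPM values are scaled by TMM and given as mean ± SD. For genes with 1 to 3 counts in wild type the ratio of summed counts is given with its exact Poisson interval at 95%, and for genes with 0 a bound against 3 counts over the group. The 1 list with such a gene kept its median of 1.78 with that gene at its bound.

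Gene lists, named-gene rule, tests and the other settings were fixed before the data were examined. There were 22 lists, 20 of which had at least 2 tested members. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2 for log2 CPM), with camera's estimated correlation and with fry beside it. Camera compares a list with the other genes, whereas fry tests it against no change. Over-representation was tested with Fisher's exact test, two-sided, against all other tested genes. Class shares were tested with the same test, TNL against CNL genes. The text names *HOS15*, *HDA9* and *PWR*; the 8 largest rises and falls past the threshold with a mean of at least 1 CPM and no overlap between groups; the 8 NLR genes with the smallest adjusted p together with *SNC1*, *RPS4* and *RRS1*; up to 3 called members of each other list; and 7 common markers. *CRK21*, AT4G16880, *NDR1*, *FLS2*, *BAK1*, *ZAT10*, *HAI1*, *HAB1*, *NYC1*, *LHCB1.1*, *RBCS1B* and *RCA* lie outside that rule and were chosen after their values were seen, as exceptions within their lists.

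The alternatives were RLE, upper quartile and library-size scaling, no filter and a filter of 1 CPM in 3 libraries, an adjusted p under 0.01, DESeq2 1.42.0, limma-voom, a replicate block and leaving out each library. Corrections for exon length and GC content were added after the data were seen. They removed a per-library loess trend (span 0.5) as an offset. The trend was fitted to the deviation of log2 CPM from the gene's mean over the libraries, against the property. Pairs of libraries within a group differed beyond the sampling noise of repeated sequencing runs of 1 library (chi-square per degree of freedom between 2.79 and 5.40), so they were not merged. This does not tell separate plants from libraries of 1 pool.

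The code was tested on simulated data, counts drawn from the means and sizes of these libraries with known changes. For *hos15-4* against wild type over 13674 simulated genes, 45.5% of 66 genes changed 1.5-fold, 71.9% of 64 changed 2-fold and 96.9% of 64 changed 4-fold were recovered. Of 147 calls 9 were false (6.12%). No list of 20 passed, and a length trend of 0.15 per doubling fell to 0.008 after the correction. Small changes were often missed in this simulation. It changed 200 genes, while 4594 were called in the data, so its adjusted threshold was stricter. These shares therefore do not give the recovery in the data. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.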

Results

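RNA was profiled by sequencing in whole shoots of 2-week-old *Arabidopsis thaliana* plants grown at 22 °C in constant light. The 6 libraries fall into 2 groups of 3, wild-type Col-0 and the mutant *hos15-4*. *HOS15* encodes a WD40-repeat protein that works with histone deacetylases, enzymes that remove acetyl groups from histones. The deposited table holds raw read counts of nuclear genes, of which 14068 had enough counts to test and 22983 did not. The wild-type libraries held 3563033, 4291282 and 4598645 counts, and the *hos15-4* libraries held 3701090, 4867774 and 5251708. On the first principal component, which carried 68.1% of the variance, the 3 wild-type libraries lay apart from the 3 mutant libraries. The labels do not say whether the 3 samples of a group came from separate plants or pools, so p-values measure only the spread between these samples.

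The targeted gene was read first. *HOS15* (AT5G67320, chromosome 5, 26857154 to 26861119) had 28, 29 and 36 counts in the wild-type libraries and 17, 29 and 21 in the *hos15-4* libraries. Its level was 8.0 ± 0.68 CPM (counts scaled to a common library size; SD, n = 3) in wild type and 4.6 ± 0.93 CPM in the mutant. The transcript fell by 0.80 on the log2 scale (SE 0.249), with adjusted p = 0.0163 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call was lost without wild-type replicate 3 (adjusted p = 0.0578), without *hos15-4* replicate 3 (adjusted p = 0.0876), with DESeq2 (adjusted p = 0.114) and with scaling by library size alone (adjusted p = 0.0556). The labels do not give the position of the lesion, so a count over the whole gene is a weak check of the genotype.

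Few genes for histone deacetylases and associated proteins passed the test. Of 19 tested, *HOS15* included, 2 rose, 1 fell and 16 did not pass the test, with the same counts adjusted over the list alone. The genes that rose were *PWR* (AT3G52250), which encodes a SANT-domain protein and had a log2 fold change of 1.43 (SE 0.233), and the deacetylase gene *HDA5* (AT5G61060; 1.08, SE 0.204). *HOS15* was the gene that fell. *HDA9*, the deacetylase named in the title of the series, had a log2 fold change of 0.36 (SE 0.240) with adjusted p = 0.266 by edgeR with Benjamini-Hochberg adjustment. Exons of *PWR* overlap those of AT3G52260, and the strand setting of the counting is not given in the sources used here, so its count is uncertain.

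The mutant shoot transcriptome differed widely from wild type. Of 14068 tested genes, 2325 rose and 2269 fell in *hos15-4*, together 32.7% of those tested. At least 2-fold changes were more often rises, with 925 genes higher and 513 lower. The largest rises included *MRD1* (AT1G53480), the cysteine-rich receptor-like kinase genes *CRK37* and *CRK7*, the receptor-like protein gene *RLP28* and the glutathione transferase gene *GSTL1*. The largest falls included the cold-induced genes *KIN1*, *COR15A*, *GOLS3* and *CBF3*.

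These calls come from edgeR's quasi-likelihood test at an adjusted p under 0.05. At an unadjusted p under 0.05, 5876 genes passed. With TMM scaling 50.6% of the calls were rises. With scaling by library size alone 71.8% were rises, with 3665 genes higher and 1438 lower, and the median log2 fold change of all tested genes moved from -0.003 to 0.17. Fold changes here are therefore relative to the bulk of the genes.

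Several of the largest rises started from almost no signal. *MRD1* had 3 counts in all wild-type libraries together and 2243 in the mutant libraries, a ratio of 596 (95% counting interval 204 to 2891). *RLP28* had 1 count against 153, a ratio of 122 (21.6 to 4847), and *CRK7* had 1 against 133, a ratio of 106 (18.7 to 4217). AT1G75945 had 2 against 442 counts (ratio 176, 48.5 to 1459), and AT2G44240 had 3 against 376 (ratio 99.9, 33.9 to 486). No wild-type library had a count for *CRK37*, AT4G10860 or *GSTL1*. Against a floor of 3 counts over the group they were at least 19.4-fold, 14.9-fold and 9.56-fold higher in the mutant. The floor leaves out the counting error of the mutant counts, and with it the 95% lower limits of these ratios are 15.4, 11.7 and 7.39. These intervals and floors cover counting error only. The wild-type counts of *RLP28*, *CRK7* and AT2G44240 all lie in 1 library each, and without wild-type replicate 3 *MRD1* had a log2 fold change of 9.85 against 9.06. *MRD1* overlaps exons of AT1G07887 and AT1G53490, which makes its count uncertain without strand. The same holds for *CBF3*, AT3G44630, *ZAR1*, *RPP1*, *SOBIR1*, *FKF1*, *RVE1*, *IAA3*, *WRKY53*, *PYK10*, *F3H*, *CHS* and *FLC*, whose exons also overlap another gene.

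Among the falls, *COR15A* dropped from 404 ± 85.4 CPM to 30.2 ± 4.27 CPM, a log2 fold change of -3.75 (SE 0.153, adjusted p = 8.95e-14 by edgeR with Benjamini-Hochberg adjustment). *KIN1* changed by -3.75 (SE 0.456), *GOLS3* by -3.51 (SE 0.496) and *CBF3* by -3.0 (SE 0.589). The value of *CBF3* was -4.83 without *hos15-4* replicate 3 and -2.39 without replicate 2. AT1G18265, for a DUF593 protein (-3.09), the uncharacterised gene AT4G13577 (-2.57), the PLAC8-family gene AT5G35525 (-2.66) and the retroelement-derived transcript *SADHU5-1* (-2.71) completed the 8 largest falls.

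**Figure D1:**
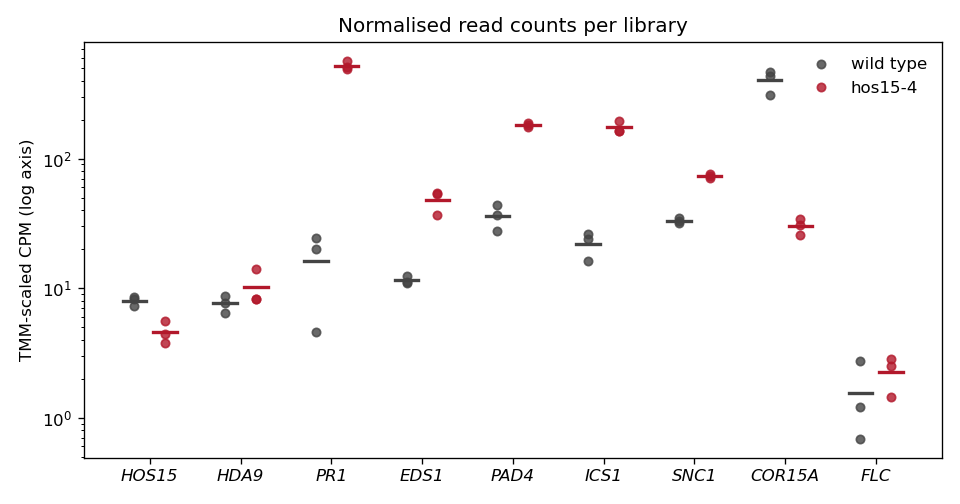
Normalised read counts (TMM-scaled CPM, log axis) of 9 named genes, with 1 point per library and a short line at each mean of 3 libraries, wild type in grey and *hos15-4* in red. *PR1* rose from a mean of 16.3 to 519 CPM and *COR15A* fell from 404 to 30.2 CPM, while *HDA9* and *FLC* did not pass the test.

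The title of the series names intracellular immune receptor genes of the NLR family, whose proteins carry a nucleotide-binding domain and leucine-rich repeats and detect pathogen effectors. Most NLR genes with enough counts to test were higher in the mutant. Of 160 listed NLR genes 86 were tested, and 65 of them rose, 1 fell and 20 did not pass. The median log2 fold change was 1.07 (95% bootstrap interval 0.88 to 1.24), and 46 genes rose at least 2-fold. Adjusted over the list alone, 72 rose. AT4G16880 was the member that fell, by 0.92 on the log2 scale.

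NLR genes were called higher in 75.6% of cases against 16.2% of the other tested genes, an odds ratio of 16.1 (95% interval 9.66 to 27.7; Fisher's exact test, two-sided, p = 1.08e-33). Fisher tests and bootstrap intervals over genes, here and below, treat genes as independent. Camera estimated correlations of 0.094 among TNL and 0.102 among CNL genes, the 2 NLR classes, so this p-value and these intervals overstate the certainty. For 73 of the 86 genes every mutant library lay above every wild-type library, which chance gives in 5% of orderings for a gene that does not differ. The share of all tested genes that separate this way was not computed, so the count cannot show whether such separation is particular to NLR genes. Of the longest 10% of tested genes 31.9% were called higher. Long transcripts were higher in the mutant as a whole (per-library values stand in the closing observations), and 65 of the 86 tested NLR genes lie among the longest 10% of tested genes. With a correction for exon length, chosen after the trend was seen, 52 of the 86 rose and the median was 0.75.

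The strongest individual NLR rises by adjusted p included AT1G31540, from 8.79 ± 0.874 to 63.5 ± 2.71 CPM (log2 fold change 2.86, SE 0.152), and AT5G41750, from 3.69 ± 0.274 to 43.9 ± 9.27 CPM (3.57, SE 0.214). AT3G44630 (2.11), AT5G36930 (1.87) and *RPP1* (1.56), a gene for resistance to downy mildew, also rose. So did *ADR1*, which encodes a helper NLR, at 2.2 (SE 0.197), *ZAR1*, which encodes a resistosome-forming NLR, at 1.37 (SE 0.124), and *RLM3* at 1.18 (SE 0.109). *SNC1* (AT4G16890, chromosome 4, 9500271 to 9505972), an NLR gene whose gain of function causes autoimmunity, rose by 1.15 (SE 0.119, adjusted p = 1.41e-07 by edgeR with Benjamini-Hochberg adjustment). *RPS4* had a log2 fold change of 0.28 (SE 0.219, adjusted p = 0.358), which turned to -0.04 with the length correction. Its head-to-head neighbour *RRS1* had 1.14 (SE 0.394, adjusted p = 0.0278 by edgeR with Benjamini-Hochberg adjustment) on 15 against 42 counts. The *RRS1* call was lost with DESeq2 (adjusted p = 0.218), with the length correction (adjusted p = 0.206) and without wild-type replicate 1, 2 or 3 or *hos15-4* replicate 2 or 3 (adjusted p of 0.0806, 0.0529, 0.115, 0.0835 and 0.0766).

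NLR genes are divided by their N-terminal domain into TNL genes, with a TIR domain, and CNL genes, with a coiled coil or RPW8 domain. Of 54 tested TNL genes 39 rose and 1 fell, with a median of 1.11, and adjusted over the list alone 43 rose and 1 fell. Of 32 tested CNL genes 26 rose and none fell, with a median of 1.01, and adjusted over the list alone 29 rose. Camera with a preset correlation placed both above other genes (adjusted p = 1.41e-17 and 3.52e-13), and each had adjusted p = 0.0683 with an estimated correlation. The shares that rose, 72.2% and 81.3%, did not differ detectably (odds ratio 0.60, 95% interval 0.17 to 1.92; Fisher's exact test, two-sided, p = 0.440). With the length correction the odds ratio was 0.363 (95% interval 0.119 to 1.02; Fisher's exact test, two-sided, p = 0.0415), which passes the threshold.

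**Figure D2:**
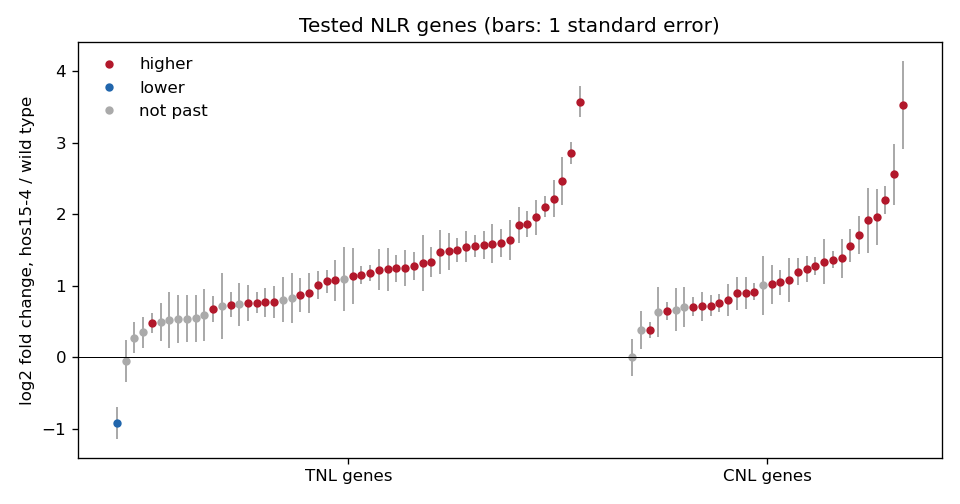
Log2 fold change of each of the 54 tested TNL and 32 tested CNL genes, ordered by value within each class, with bars of 1 standard error. Red points rose, blue fell and grey did not pass the test, with 65 red, 1 blue and 20 grey points.

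Salicylic acid is the hormone that drives much of the defence against biotrophic pathogens. Of 26 tested genes for its synthesis and signalling, 25 rose and none fell, with a median log2 fold change of 2.67. *ICS1*, the main enzyme of its synthesis, rose from 22.0 ± 5.28 to 174 ± 19.1 CPM (log2 fold change 3.0, SE 0.15). *PAD4* rose by 2.35 (SE 0.135), *EDS1* by 2.07 (SE 0.173) and *DMR6*, a salicylic acid hydroxylase gene, by 2.71 (SE 0.163). *NDR1* had 0.24 and did not pass. Adjusted over the list alone 25 rose. The list passed camera with a preset correlation at adjusted p = 6.62e-18, and adjusted p = 0.0988 with an estimated correlation.

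Genes induced downstream of salicylic acid rose as well. Of 18 tested pathogenesis-related and salicylic acid-induced genes 17 rose and none fell, with a median of 3.0, and adjusted over the list alone 17 rose. *PR1*, the usual marker of the response, rose from 16.3 ± 10.3 to 519 ± 39.0 CPM (log2 fold change 5.03, SE 0.255, adjusted p = 2.04e-12 by edgeR with Benjamini-Hochberg adjustment). *PR5* rose by 3.58 (SE 0.179), the receptor-like kinase gene AT1G35710 by 3.24 (SE 0.147) and AT1G13470 by 3.52 (SE 0.171). For this list camera with a preset correlation gave adjusted p = 3.67e-14, and adjusted p = 0.168 with an estimated correlation.

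Cell-surface and signalling components moved in the same direction. Of 22 tested cysteine-rich receptor-like kinase genes 16 rose and *CRK21* fell, with a median of 1.78 (1.17 without wild-type replicate 3), and adjusted over the list alone 17 rose and 1 fell. *CRK6* (3.35, SE 0.187) and *CRK4* (3.35, SE 0.234) rose about 10.2-fold. *CRK7* is also a member of the salicylic acid-induced list. Of 16 tested genes of pattern-triggered immunity, the defence set off by microbial molecules at the cell surface, 11 rose and none fell, with a median of 0.95, and adjusted over the list alone 12 rose. *SOBIR1* (2.07, SE 0.143), *BIR1* (1.82, SE 0.127) and *WRKY18* (3.15, SE 0.251) rose, while the receptor gene *FLS2* (0.34) and its co-receptor gene *BAK1* (0.15) did not pass. The preset correlation of camera gave adjusted p = 2.86e-10 for the kinases and 6.31e-07 for pattern-triggered immunity, and adjusted p = 0.0683 and 0.160 with an estimated correlation.

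Genes for defence metabolites rose in part. Of 11 tested genes for camalexin, an antimicrobial indole, and indole glucosinolates, 10 rose and none fell, with a median of 1.42, and adjusted over the list alone 10 rose and 1 fell. The median was 0.65 with the stricter filter and with DESeq2, where the list still passed camera (adjusted p = 7.3e-04 and 8.6e-04). *GSTF6* (2.19, SE 0.155), *MYB51* (1.64, SE 0.197) and *CYP71A12* (3.35, SE 0.445) rose. Of 10 tested anthocyanin and flavonoid genes *F3H* (1.03), *CHS* (0.79) and *DFR* (0.62) rose and 7 did not pass, also adjusted over the list alone, where 3 rose. Of 8 tested aliphatic glucosinolate genes *MYB29* (0.61) and *CYP79F1* (0.55) rose and 6 did not pass, also with 2 adjusted over the list alone. Camera with a preset correlation gave adjusted p = 4.55e-05, 0.0258 and 0.177 for these lists, and adjusted p = 0.168, 0.311 and 0.622 with an estimated correlation. The anthocyanin list was lost with the stricter filter (adjusted p = 0.0599), with DESeq2 (0.0601), without wild-type replicate 2 (0.0518) and without *hos15-4* replicate 1 (0.0776). The *DFR* call was lost without wild-type replicate 3 (adjusted p = 0.0638). The *CYP79F1* call was lost without wild-type replicate 2 (0.0651), without *hos15-4* replicate 3 (0.0553) and with the length correction (0.121).

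Genes of the cold and abscisic acid response were mostly lower in the mutant. Of 20 tested members 13 fell, 3 rose and 4 did not pass, with a median log2 fold change of -1.16 and the same numbers of rises and falls adjusted over the list alone. *KIN2* fell from 1824 ± 465 to 408 ± 68.7 CPM (log2 fold change -2.16, SE 0.149), and *COR413PM1* changed by -1.50 (SE 0.107). The members that rose were *ZAT10* (1.3), a stress-induced zinc finger gene, and the phosphatase genes *HAI1* (1.39) and *HAB1* (1.53), which encode negative regulators of abscisic acid signalling. The list passed camera with a preset correlation at adjusted p = 1.52e-05, and adjusted p = 0.292 with an estimated correlation.

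Nuclear photosynthesis genes fell by modest amounts and almost without exception. Of 31 tested members 28 fell and none rose, with a median of -0.56, and adjusted over the list alone 28 fell. *PSAF* fell from 8313 ± 633 to 4542 ± 93.5 CPM (log2 fold change -0.87, SE 0.090), *PSBW* changed by -0.92 (SE 0.091) and *PSAK* by -0.87 (SE 0.094). *LHCB1.1*, *RBCS1B* and *RCA* did not pass. The median member has 1268 exonic bases, on the short side of a trend in which short transcripts were lower in the mutant. After the length correction 26 fell and the median was -0.46, and with library-size scaling 24 fell and the median was -0.38. Camera with a preset correlation gave adjusted p = 6.96e-11, and adjusted p = 0.0683 with an estimated correlation.

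**Figure D3:**
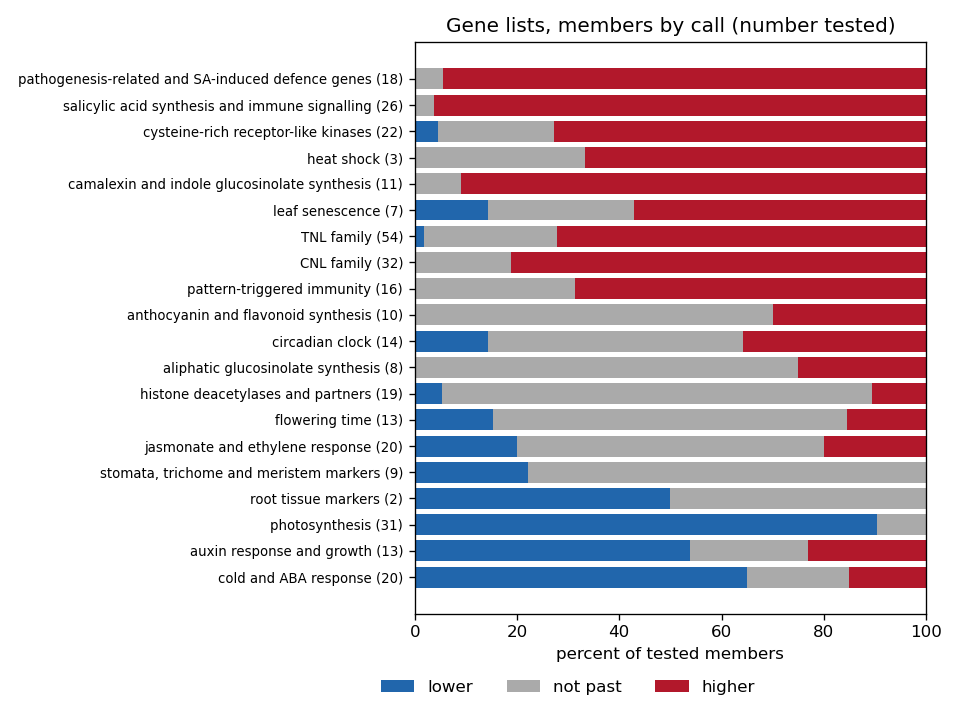
Percent of the tested members of each of 20 gene lists that fell (blue), did not pass (grey) or rose (red), with the number tested in brackets and lists ordered by median log2 fold change. The salicylic acid list has 25 of 26 members in red and the photosynthesis list 28 of 31 in blue.

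Growth, clock and development lists went both ways. Of 13 tested auxin and growth genes 7 fell and 3 rose, and adjusted over the list alone 8 fell and 3 rose. The falls included *EXPA8* (-0.99), *IAA3* (-0.83) and *SAUR21* (-1.46), and the list did not pass camera with a preset correlation (adjusted p = 0.0724) or with an estimated one (adjusted p = 0.292 with an estimated correlation). It passed without wild-type replicate 3 (adjusted p = 0.0320), without *hos15-4* replicate 2 (0.0291) and without *hos15-4* replicate 3 (0.0294). It also passed camera with DESeq2 (adjusted p = 0.0334), limma-voom (0.0276), the replicate block (0.0347), library-size scaling (0.0168), no filter (0.00599) and the stricter filter (0.0417). Fry, which asks the different question of change against none, gave adjusted p = 0.0259. Of 14 tested clock genes 5 rose and 2 fell (adjusted p = 0.177 by camera), and 6 rose and 3 fell adjusted over the list alone. *LHY* (1.25), *RVE8* (1.26) and *RVE1* (1.16), which peak around dawn in light-dark cycles, rose.

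Of 20 tested jasmonate and ethylene genes 4 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.452 by camera). *AOS* (-0.93) and *CORI3* (-1.58) fell and *AOC3* (2.1) rose, and the list's median of -0.25 and its test point down while its mean is 0.03. Of 13 tested flowering-time genes 2 rose and 2 fell (adjusted p = 0.732 by camera), and 1 rose and 2 fell adjusted over the list alone. *SPL9* (-1.41) and *FKF1* (-0.85) fell and *SOC1* (0.62) rose. *FLC* had 0.50 (SE 0.474, adjusted p = 0.448 by edgeR with Benjamini-Hochberg adjustment) and 1.23 without wild-type replicate 2 (adjusted p = 0.116), *GI* had -0.46 (SE 0.290, adjusted p = 0.242) and *FT*, with 8 counts against 24, was not tested. With the length correction *GI* passed, at -0.81 (adjusted p = 0.0351). The *SPL9* call was lost with DESeq2 (adjusted p = 0.0896) and without wild-type replicate 3 (0.0644), and that of *SOC1* with DESeq2 (0.0604) and without wild-type replicate 2 (0.0738) or *hos15-4* replicate 1 (0.0977).

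Of 7 tested leaf senescence genes 4 rose and 1 fell, also adjusted over the list alone. *SAG13* (3.49), *WRKY53* (2.41) and *SGR1* (1.13) rose, and *NYC1*, for a chlorophyll b reductase, fell. The size of the *SAG13* rise rests on few wild-type counts (2, 6 and 38), and it was 5.29 without wild-type replicate 3 and 4.18 with limma-voom. Of 3 tested heat shock genes *HSP70* (1.63) and *HSP90.1* (2.07) rose, also adjusted over the list alone. Camera with a preset correlation gave adjusted p = 0.0440 and 0.0230 for these lists, and both had adjusted p = 0.272 with an estimated correlation. Both calls were lost without wild-type replicate 1 (adjusted p = 0.0817 for each), without wild-type replicate 2 (0.0638 and 0.125) and without *hos15-4* replicate 1 (0.0875 for each). The senescence list was also lost with library-size scaling (adjusted p = 0.0954) and the replicate block (0.0619), and the heat shock list with DESeq2 (0.0615), no filter (0.0657) and the stricter filter (0.0599).

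Most floral, seed and root markers had too few counts to test. None of the 9 floral and 15 seed markers had enough counts to test. Of 11 root markers 2 were tested, with adjusted p = 0.207 by camera. Of these *PYK10*, a beta-glucosidase gene, fell from 63.0 ± 7.22 to 29.8 ± 2.42 CPM. Its log2 fold change was -1.09 (SE 0.131), and it also fell adjusted over the list alone. Of 9 tested stomatal, trichome and meristem markers *CLV1* (-0.36) and *KAT1* (-0.71) fell and 7 did not pass, with 2 lower adjusted over the list alone. Against other genes the list did not pass (adjusted p = 0.105 by camera), and against no change it did (adjusted p = 0.0252 by fry). The *KAT1* call was lost without each of wild-type replicates 2 and 3 and *hos15-4* replicates 1, 2 and 3, and that of *CLV1* without wild-type replicate 1 and *hos15-4* replicates 2 and 3. Both were lost with DESeq2 (adjusted p = 0.165 and 0.0586) and library-size scaling (0.112 and 0.220).

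In all, camera with a preset correlation put 12 of 20 tested lists past the threshold, and 0 with an estimated correlation, where 8 lists had adjusted p between 0.0683 and 0.168. Those 12 lists also passed fry, which tests a list against no change and not against other genes (adjusted p from 0.00049 to 0.0407).

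**Figure D4:**
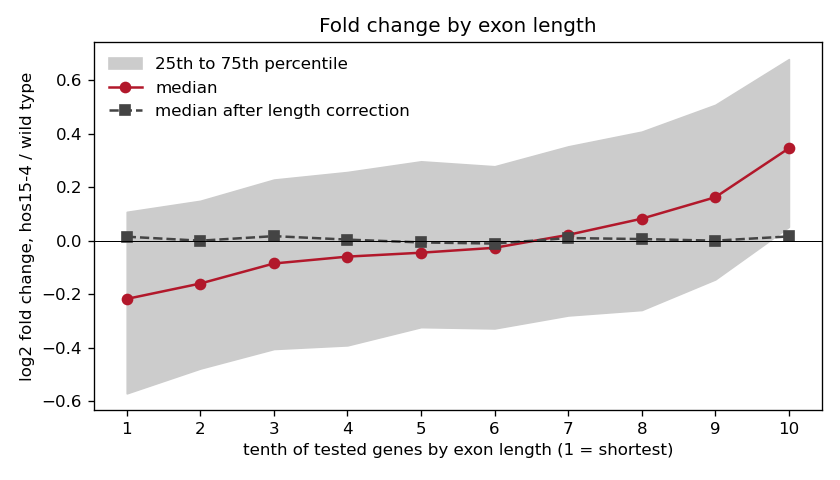
Log2 fold change against exon length, with tested genes sorted into 10 equal groups from the shortest (1) to the longest (10). The red line is the median, the grey band runs from the 25th to the 75th percentile and the dashed line is the median after the length correction. The median runs from -0.22 in the shortest group to 0.35 in the longest.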

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

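The length and GC corrections, the NLR list by product text and the NLR list without near-identical copies were chosen after the data were seen. The counts of genes that rose or fell stayed within 1.5 times under every alternative except scaling by library size alone, which gave 3665 rises, 1438 falls and 281 falls of at least 2-fold, because it lets the bulk of genes shift upward. Leaving out 1 library gave 1795 to 2269 rises, 1798 to 2162 falls and 58 to 68 NLR genes higher. DESeq2 gave 1657 and 1573, and the length correction 2251 and 2052, with 3749 of the 4594 original calls kept. The NLR odds ratio lay between 8.19 (length correction) and 18.9 (without *hos15-4* replicate 1) and passed under every alternative. TNL against CNL shares passed only with the length correction, at an odds ratio of 0.363, and the cause was not tested. Tested TNL genes were longer, with a median of 4169 exonic bases against 3289 for CNL genes. With the correction TNL rises went from 39 to 28 and CNL rises from 26 to 24. With an estimated correlation 0 lists passed camera. How much of that loss comes from the members' correlation was not tested. The cysteine-rich receptor-like kinases had an estimated correlation of 0.0273 against the preset 0.01. Their unadjusted camera p went from 8.59e-11 to 0.00469. For the stomatal, trichome and meristem list the estimate was lower than the preset, at -0.0304. Its unadjusted camera p still rose from 0.0736 to 0.137, so a higher correlation does not account for every larger p. The flowering-time list turned positive without a filter (0.11), with the stricter filter (0.24), with DESeq2 (0.24) and, in its median alone, with library-size scaling (0.11), and its test direction turned with the GC correction (median -0.066). The root list turned positive without a filter (0.23), where more genes are tested, and its median was 0.093 with the stricter filter. The heat shock median of 1.63 lay between 0.69 and 1.04 without a filter, with the stricter filter, with DESeq2 and without wild-type replicate 2 or *hos15-4* replicate 1. *RPS4* turned to -0.039 with the length correction. The flowering-time list, the root list and *RPS4* had not passed the threshold, whereas the heat shock list had and lost its call under each setting named for it. The labels name no pairing by replicate number. The correlations of same-numbered deviations were 0.102, 0.135 and 0.051, against -0.110 to 0.001 for different numbers, so a weak pairing cannot be excluded. With the replicate block 2467 genes rose and 2415 fell, 65 NLR genes were higher, and each wild-type library correlated best with its own number, a hint from the data and not the design. Leaving out organelle genes was not run, as the table used lists none.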

Other observations

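The gene families in this paragraph and the next were chosen after the data were seen, and all 9 that were looked at are given. Cell-surface receptor genes rose beyond the kinases described in the report. Of 26 tested receptor-like protein genes 18 rose and 3 fell, with a median log2 fold change of 2.07, among them *RLP41* (3.48, SE 0.197), *RLP23* (3.17, SE 0.180) and *RLP39* (4.37, SE 0.289). Of 5 tested wall-associated kinase genes 4 rose, led by *WAK3* (4.88, SE 0.276). Of 26 tested WRKY transcription factor genes 17 rose and none fell, with *WRKY46* at 3.39 and *WRKY51* at 4.09. Members such as *WRKY46*, *WRKY18*, *WRKY53*, *RLP23* and *WAK1* also belong to lists tested above, so these families are not separate evidence. Of 7 tested calmodulin-like genes 4 rose and 1 fell, with *CML41* at 3.79. Genes for protein folding in the endoplasmic reticulum also rose, 14 of 20 with none lower, including *BIP3* (4.04, SE 0.220) and the calreticulin gene *CRT3* (2.15, SE 0.115). A first name pattern for this family also caught unrelated genes such as those for molybdenum cofactor synthesis and gave 16 rises and 1 fall among 30. Camera with a preset correlation gave adjusted p = 8.65e-10, 8.75e-05, 3.84e-08, 0.00259 and 1.30e-07 for the receptor-like proteins, wall-associated kinases, WRKY, calmodulin-like and folding genes. These had adjusted p = 0.0845, 0.0901, 0.0845, 0.0943 and 0.116 with an estimated correlation. Because the families were picked after their values were seen, the p-values here and in the next paragraph are descriptive only.

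The other families were mixed. Of 27 tested glutathione transferase genes 10 rose and 4 fell (adjusted p = 0.0289 by camera, adjusted p = 0.259 with an estimated correlation), which became 13 and 2 after the length correction and 14 and 2 under library-size scaling. Of 6 tested *SADHU* retroelement transcripts 4 fell, with *SADHU4-1* at -2.20 (adjusted p = 0.0213 by camera, adjusted p = 0.118 with an estimated correlation). Of 76 small nucleolar RNA genes 15 fell and 3 rose (adjusted p = 0.0184 by camera, adjusted p = 0.484 with an estimated correlation), which became 7 and 8 after the length correction. Of 283 tested genes whose product text names a ribosomal protein or its family 55 fell and 18 rose (adjusted p = 0.107 by camera), which became 24 and 52 after that correction, and 25 and 71 under library-size scaling, where the median of -0.02 became 0.16. That text also covers plastid ribosomal proteins and genes that are not ribosomal, such as the elongation factor gene *LOS1* and *MEE5*, which are among the rises.

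Among the 10 ways to part the 6 libraries into 3 and 3, the real one gave 4594 changed genes and the highest other gave 0 by edgeR's quasi-likelihood test, so 1 split was as large. For NLR genes moving one way the real split gave 65 and the highest other 0, again 1 split. For the list tests the real split gave 12 and the highest other 12, so 2 splits were as large. With 10 splits no share can fall under 0.05, and the mixed splits carry the genotype difference as spread within their groups and keep a part of it between them.

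In the tests below, the one on the 25th percentile was written after related values had been seen, and the length correction was chosen after the length trend was seen. The first pattern is the rise of NLR genes. Length-dependent recovery of RNA would bring their median near 0 once length is corrected, but it stayed at 0.75 (95% bootstrap interval 0.56 to 0.94), down from 1.07, so length may carry part of the rise and not all of it. Other genes matched on length and level, 50 for each NLR gene, had a median of 0.30, and the highest median among 10000 random matched sets was 0.52. The random sets also treat genes as independent. Whether reads shared between near-identical copies play a part is left open, because 1 tested gene had a copy and the share of 75.3% that rose without it could not have differed much from 75.6%. The genotype stays open as a biological explanation that the design cannot part from anything else that differed between the groups.

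The second pattern is that longer transcripts were higher in the mutant (Spearman correlation 0.28 across genes, which are not independent replicates). A minority of long induced genes would leave the lower part of the distribution in place, but the 25th percentile differed by 0.62 between the longest and the shortest 10% of genes (95% bootstrap interval 0.58 to 0.67). For each library, the deviation of log2 CPM from the gene's mean over all libraries was regressed on log2 length. The slopes were -0.13, -0.07 and -0.07 in wild type and 0.04, 0.10 and 0.14 in the mutant. Their signs are therefore relative to the other libraries. The slopes of the groups did not overlap, but the gap, 0.103, barely exceeded the widest range within a group, 0.098. The slopes rose with replicate number in both groups, so that range may hold a shared part. The excess had a bootstrap interval of -0.017 to 0.026, which was added once the gap was seen. That bootstrap resamples genes and does not measure the spread between libraries, so it cannot decide on RNA quality. Differences in RNA quality between single libraries remain possible. Whether the trend belongs to the genotype or to library handling cannot be told apart, because each group is one genotype and an exact permutation test of 3 against 3 cannot go below 0.1.

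The third pattern is the fall of cold-response genes, for which length-dependent recovery does not account, since after the length correction the median was -1.15 with 13 of 20 members still lower. A difference in circadian phase at harvest remains a candidate explanation. The tested morning genes *CCA1*, *LHY* and *RVE8* had a median of 1.25. The evening genes *TOC1*, *ELF4*, *LUX* and *GI* had a median of -0.62, opposite in sign as the prediction for a phase shift required. The test compared clock genes only, so it cannot tie a phase shift to the fall of the cold-response genes. Of the evening genes *LUX* (-0.87) and *ELF4* (-0.77) fell while *GI* (-0.46) and *TOC1* (0.07) did not pass, and with the length correction *LUX* (-1.18) and *GI* (-0.81, adjusted p = 0.0351) passed while *ELF4* (-0.50, adjusted p = 0.0517) and *TOC1* (-0.08) did not (*PRR9* was not tested, and the value of *GI* was known when the test was written). The plants grew in constant light and the labels give no harvest time. An effect of the genotype on the clock, a difference in harvest time and an effect of the genotype apart from the clock all stay open.

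One hypothesis was that the rise spreads over the chromosomal neighbourhood of NLR genes. All 160 listed NLR genes were used, tested or not. Of 277 tested non-NLR genes within 10 kb of an NLR gene 14.8% rose, against 16.2% of the other non-NLR genes (odds ratio 0.90, Fisher's exact test, two-sided, p = 0.621). No excess was seen near the listed NLR genes as a whole. Of those NLR genes 65 rose and 74 were not tested, so the comparison cannot decide on spreading from the genes that rose. Another hypothesis was that NLR genes in physical clusters rise more often than single ones. With another NLR gene within 50 kb 70.7% of 58 rose, against 85.7% of the 28 others (odds ratio 0.41, Fisher's exact test, two-sided, p = 0.182), so the difference ran the other way and did not pass the threshold.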
